A study of Mus musculus with 12 samples.

How the data were processed

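RNA was measured in 12 libraries of mouse C57BL/6 embryonic stem (ES) cells, labelled male, in 6 groups of 2 libraries (Smchd1 fl/fl and Smchd1 del/del at day 1, day 5 and day 8). Per the labels' protocols, each ES line came from 1 blastocyst and was split, with 1 part left untransduced (fl/fl) and the other transduced with a retrovirus carrying Cre and a puromycin gene and then selected with puromycin (del/del). The controls were therefore untransduced and unselected, so the deletion is confounded with transduction and selection in every comparison of genotypes. Replicate 1 is line 1 and replicate 2 is line 3 at every day, per the column names. The first sampling is called day 1 in the labels and day 0, before differentiation, in the protocol; it is called day 1 here.

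Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.12 and edgeR were used with genome build mm10; the role of each, and whether duplicate reads were removed, is not given in the sources used here. The deposited table holds log2 RPM (reads per M reads, where M is mega), per the labels, for 25965 genes in 12 columns, and no column was left unused. Taken out of the log2, the deposited values of each library are whole multiples of 1 step, within 0.02 reads for 100% of genes, with genes of 0 reads entered as 0.9 reads. Read numbers and the denominator of each library were recovered from these steps. The denominators were 14.9 to 34 M reads, of which 1.51 to 8.67 M (10.1 to 27.8%) lay in the genes of the table, so the deposited scale divides by reads outside the genes too. The 13 mitochondrial transcripts in the table had 0 reads in all libraries. Of 25899 distinct gene names, 24631 (95.1%) matched the GENCODE M21 annotation, which gave exon lengths and overlaps; coordinates are the deposited mm10 ones. 66 gene names occurred more than once.

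The following were fixed before the data were examined: the groups, comparisons, tests, the alternative settings, 43 gene lists and the naming rule. Genes with a deposited log2 value above 0 in at least 2 libraries were tested, which kept 14063. A linear model with 6 group means and a mean-variance trend was fitted with limma 3.58.1 in R 4.3.3, and moderated p-values were adjusted with the Benjamini-Hochberg method over all tested genes at 0.05. Contrasts were del/del minus fl/fl at each day and averaged over days, the differences of this effect between days (interactions), and day 5 against day 1 and day 8 against day 5 within each genotype. Chromosomes with at least 20 tested genes were compared by camera.

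The planned fit used the deposited scale. On it the median gene moved with the share of reads in genes: the median log2 difference between genotypes was 0.15 at day 1, -0.40 at day 5, 0.90 at day 8 and 0.22 over the days, and -0.55, 0.73 and 1.29 in the interactions of day 5 and day 1, day 8 and day 1, and day 8 and day 5. Changes are therefore reported relative to the median gene, from the alternative in which each library was rescaled by the median of its log ratios, with the counts on the deposited scale beside them. This choice was made after these shifts were seen. Tests on simulated reads (200 genes changed, 50 at each fold size, dispersion 0.08) took the shift of each library as technical. They show what such a shift does to the calls, and cannot show that the real shifts are technical. For the day 8 contrast of genotypes, 210 of 342 genes called on the deposited scale were unchanged ones, against 7 of 149 on the relative scale. In that simulation of 14078 tested genes the relative scale recovered 8% of 2-fold, 78% of 4-fold, 98% of 8-fold and 100% of 16-fold changes. At day 1 (14093 genes) the shares were 8, 86, 96 and 98%, and at day 5 (14074 genes) 6, 76, 92 and 100%. The same dispersion was used for all genes and days, so these shares need not hold in the data. Few calls do not rule out large changes: at day 5 Chit1 was 7.77-fold higher with an adjusted p of 0.597 by limma.

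The naming rule took Smchd1, then for each comparison of genotypes the 8 largest increases and 8 largest decreases among genes with an adjusted p under 0.05 on the deposited scale whose del/del libraries all lay on 1 side of the fl/fl libraries at that day (at each day, for the mean over days), and the 5 largest per direction for time comparisons. With fewer than 3 passing genes, up to 3 with the smallest unadjusted p were added as values. The rule named up to 4 members with the smallest p of each list discussed, any Hox gene, and the 5 smallest p of each interaction. Predicted genes, clones, pseudogenes and small RNA genes were not named.

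Each list with at least 4 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and beside it with camera at an estimated correlation and with fry. The lists were Hox genes (3-prime, paralogs 1 to 5; middle, 6 to 9; 5-prime, 10 to 13; all; and the Hoxa, Hoxb, Hoxc and Hoxd clusters), naive pluripotency, primed pluripotency, neuromesodermal progenitor (NMP) and caudal epiblast, paraxial mesoderm, neural progenitor, postmitotic neuron, lateral and intermediate mesoderm, definitive endoderm, extraembryonic endoderm, trophoblast, fibroblast feeder, endothelium and blood, 2-cell-like, germline, imprinted, Snrpn cluster, Igf2r cluster, Pcdh alpha, Pcdh beta, Pcdh gamma, Polycomb components, DNA methylation and silencing, chromatin architecture, p53 targets, interferon response, stress and heat shock, glycolysis and hypoxia, Wnt targets, FGF and ERK targets, retinoic acid signalling, Gdf11 and TGF-beta targets, cell cycle, replication histones, mitochondrial transcripts and Y-linked. A gene's call over all genes and its call adjusted over the list alone are both given. Of the list calls on the relative scale with the filter, only that of the Gdf11 and TGF-beta targets between day 8 and day 5 of del/del (adjusted p = 0.0271) held with an estimated correlation, so every other list call rests on the preset.

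The alternative settings fixed then were a replicate block, no filter, a stricter filter (above 2, 11209 genes), a pseudocount of 1, median of log ratios, quantile normalization, no trend, a robust fit, array weights, fits of 1 day only and leaving out each library. Chosen after the data were seen were voom on the recovered reads, and the relative scale with a replicate block, with a crossed block, without the shallow fl/fl day 8 library of line 3, without the del/del day 5 library of line 3, with a GC and length trend removed, and with a read density trend removed. For the lists, the relative scale with no filter and the estimated correlation with no filter were added too. No negative binomial count test was run, since the deposited unit is log2. The numbers pair the samples, since both genotypes of a number come from 1 line. The correlation of the paired residuals was 0.13 at day 1, -0.15 at day 5 and -0.11 at day 8, and the planned fit without the block was kept. Such values over all genes do not settle whether pairing matters for single genes. Counts with the block are given with the other settings.

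Errors after ± are standard errors of the model (n = 2 libraries per group). Ratios of reads pool the libraries of a group, scaled to the median gene, with 95% exact (Clopper-Pearson) intervals. Where a group had 0 reads in both libraries, a lower bound was computed against a floor of 3 reads per library. Intervals and floors cover counting error only. P-values measure only the spread between these samples, which come from 2 lines, and nothing in the labels says that they were separate cultures. Simulations and draws used seed 1.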

Results

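RNA was sequenced from mouse ES cells, labelled male, during differentiation towards neuromesodermal progenitors, bipotent cells of the caudal embryo, and onwards, with the chromatin protein gene Smchd1 either floxed or deleted. Each of the 6 groups (2 genotypes by 3 days) held 2 libraries, from line 1 and line 3. Gene reads were 7.67 and 8.67 M in the del/del and 6.42 and 7.14 M in the fl/fl libraries at day 1. They were 4.78 and 3.99 M against 4.36 and 7.60 M at day 5, and 8.11 and 7.57 M against 5.97 and 1.51 M at day 8, each pair given as line 1, then line 3. The shallowest library, fl/fl day 8 of line 3, limits the day 8 control group. Without it 299 genes were called at day 8 relative to the median gene, against 2109 with it, and 269 were shared. Days parted the libraries on the first principal component (66.3% of the variance), with coordinates of -127.8 to -118.9 at day 1, 37.2 to 41.9 at day 5 and 73.5 to 91.5 at day 8. On the second (12.2%), del/del libraries lay at 58.8 and 78.2 at day 8 and fl/fl libraries at -12.2 and -57.3. At day 5 the del/del library of line 3 lay at 15 and the other 3 at -40.5 to -33.3.

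Smchd1 (chromosome 17, 71344489 to 71475343, mm10), the targeted gene, was lower in every del/del library than in every fl/fl library of its day. It had 197 and 271 reads in del/del against 1212 and 1495 in fl/fl at day 1, 102 and 104 against 366 and 919 at day 5, and 161 and 140 against 728 and 111 at day 8. Relative to the median gene its level was 2.32 and 2.57 against 5.23 and 5.36 at day 1, 2.05 and 2.38 against 4.05 and 4.52 at day 5, and 1.92 and 1.82 against 4.60 and 3.99 at day 8 (log2 RPM). Smchd1 fell 7.18-fold at day 1 (log2 -2.84 ± 0.24, adjusted p = 0.00187), 4.21-fold at day 5 (-2.07 ± 0.24, adjusted p = 0.043) and 5.38-fold at day 8 (-2.43 ± 0.24, adjusted p = 0.00229). The mean over days was -2.45 ± 0.14 (adjusted p = 2.99e-05), lower in 6 of 6 pairs. On the deposited scale the differences were -2.69 (adjusted p = 0.449), -2.45 (0.752), -1.55 (0.037) and, over the days, -2.23 (0.00273). With a replicate block the adjusted p at day 5 was 0.137, and without the del/del day 5 library of line 3 it was 0.205, so the day 5 call was lost in both. Over all settings on the relative scale it ranged from 0.0095 to 0.205. Reads outside the deleted part of the gene remain countable, so those left do not measure undeleted cells.

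**Figure D1:**
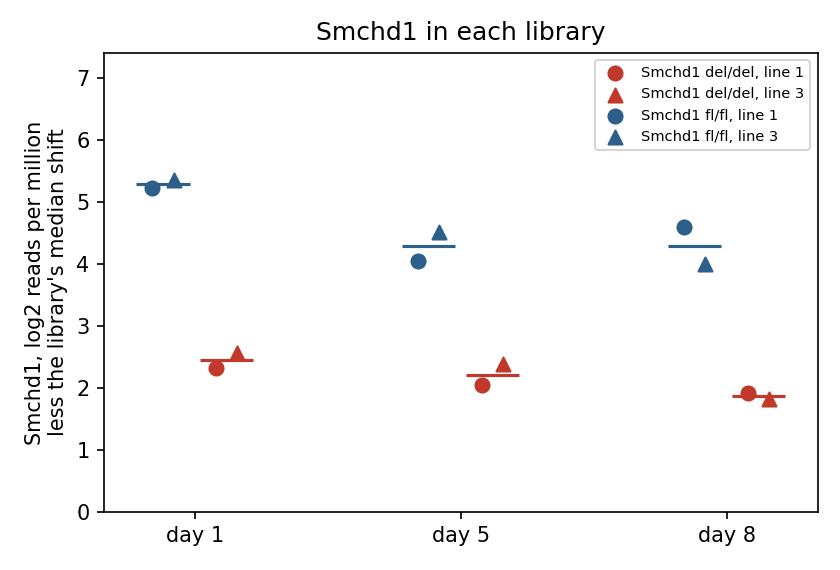
Smchd1 in each of the 12 libraries, as log2 RPM less the median shift of the library, by day and genotype. Del/del libraries lie between 1.82 and 2.57 and fl/fl libraries between 3.99 and 5.36.

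Before differentiation, the comparison asks what the deletion changes in ES cells labelled male. Besides Smchd1, no gene passed the test at day 1. The largest contrasts among the genes with the smallest p were Hoxb3os at 2.65 ± 0.81, an antisense transcript with 76.2% of its exons shared with Hoxb3 and Hoxb2, Ano1 at 2.42 ± 0.71 and the adaptor gene Shd at 2.33 ± 0.64, all higher in del/del. Their reads were 6.21-fold (95% interval 1.88 to 32.3), 13-fold (2.01 to 544) and 5.17-fold (2.43 to 12.6) higher. Atxn1 was lower by 2.64 ± 0.67 (4.94-fold in reads, 1.97 to 14.8) and the Wnt ligand gene Wnt4 by 2.07 ± 0.45 (4.16-fold, 2.35 to 7.80), each with an adjusted p of 1.

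The limma test called 0 genes higher and 1 lower at day 1 (170 at an unadjusted p under 0.05), voom also 0 and 1, and the deposited scale 0 (79 unadjusted). In a fit with array weights 43 genes were higher and 13 lower. The 2-cell-like list, Zscan4 genes of the totipotent-like state among them, had a median of 0.85 with 7 of 8 tested genes positive and none past the test (camera adjusted p = 0.00652), Arg2 being at 1.16 ± 0.62. Germline genes had 0.27 (19 of 20 positive, none past the test, adjusted p = 0.00521), Gdf11 and TGF-beta targets 0.23 (13 of 15 positive, none past the test, adjusted p = 0.00475, adjusted p = 0.242 with an estimated correlation). The fibroblast list had -0.31 (-0.05 with genes of 0 reads at their bound, adjusted p = 0.00752), FGF and ERK targets -0.13 (adjusted p = 0.00687, 0.03 on the deposited scale), middle Hox genes -0.38 (bound -0.26, adjusted p = 0.00854) and the Hoxb cluster -0.50 (bound -0.46, 1 gene higher and 1 lower adjusted over the list alone, adjusted p = 0.0366). Col4a2, at -1.30 ± 0.29 in the extraembryonic endoderm list, was the gene of that list below 0.05 when adjusted over the list alone. The other lists did not pass at day 1. Without the fl/fl day 1 library of line 1 camera called 3 lists, against 7 with all libraries, and each of the 7 lost its call without at least 1 library of day 1 (adjusted p up to 0.924).

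At day 5, after Wnt activation by the Gsk3 inhibitor, the comparison asks whether the deletion alters entry into the neuromesodermal state. Hox genes, which pattern the body axis and open from 3-prime to 5-prime, were higher as a list in del/del, with a median of 0.85 and 32 of 38 genes positive. The medians were 0.96 in the 3-prime group (14 of 14 positive), 0.96 in the middle group (12 of 12) and -0.10 in the 5-prime group, and the groups were not tested against each other. Hoxb3 was higher by 1.61 ± 0.73, Hoxd8 by 1.43 ± 0.59 and Hoxb7 by 0.96 ± 0.44, none past the test. In the imprinted Snrpn cluster, Peg12 (1.28 ± 0.46), Mkrn3 (1.11 ± 0.33) and Ndn (0.69 ± 0.23) were higher, all 3 below 0.05 when adjusted over the list alone. The genes with the smallest p were Chit1 at 2.96 ± 0.78 (9.27-fold in reads, 2.75 to 48.7), Cxcl12 at 2.36 ± 0.70 (6.52-fold, 4.60 to 9.47), Rbm44 at 2.35 ± 0.49 (4.77-fold, 1.99 to 13.1), Slc27a2 at -2.46 ± 0.43 (5.40-fold lower, 1.90 to 21.1) and Abca5 at -3.16 ± 0.93 (4.11-fold lower, 2.44 to 7.33), each with an adjusted p of 0.597.

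By limma only Smchd1 passed over all genes at day 5 (1088 at an unadjusted p under 0.05); voom and the deposited scale called 0 (485 unadjusted on the latter). Camera called the Hox list (adjusted p = 0.000423, adjusted p = 0.858 with an estimated correlation), its 3-prime (0.00464) and middle (0.000423) parts but not the 5-prime part (0.802), the Hoxb (0.86, adjusted p = 0.0134) and Hoxd (1.01, adjusted p = 0.0134) clusters, and the Snrpn cluster (0.40, adjusted p = 0.0124). Also called were fibroblast genes (0.45, adjusted p = 0.0134), cell cycle genes (0.16, adjusted p = 0.0134) and imprinted genes (0.13, adjusted p = 0.0368). The medians of the last 2 on the deposited scale were -0.21 and -0.24. Among Gdf11 and TGF-beta targets, Id3 (0.86 ± 0.18), Id2 (0.86 ± 0.24) and Smad6 (1.08 ± 0.34) were higher and Lefty1 (-1.30 ± 0.36) lower when adjusted over the list alone, and the list did not pass (adjusted p = 0.693). At day 5 camera called 9 lists with all libraries, 3 without the fl/fl library of line 3 and 0 without the del/del library of line 3, where the Hox list had an adjusted p of 0.977. The replicate libraries of day 5 had a Spearman correlation of 0.943 in del/del and 0.981 in fl/fl.

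At day 8, after Gdf11, which moves cells towards posterior identity, Hox genes were higher in del/del along all 4 clusters. Of 38 tested Hox genes 37 had a positive difference, Hoxb4 (-0.22) being the exception, and the median was 2.14. Among posterior genes, Hoxd12 rose by 4.11 ± 0.79 (adjusted p = 0.0143), Hoxc12 by 3.78 ± 0.82 (0.0186), Hoxd13 by 3.54 ± 0.73 (0.0165), Hoxc11 by 3.42 ± 0.74 (0.0187) and Hoxa11 by 2.03 ± 0.48 (0.0239). Among anterior and middle genes, Hoxc4 rose by 3.38 ± 0.77 (0.0214), Hoxb1 by 3.28 ± 0.73 (0.02) and Hoxa6 by 3.86 ± 1.02 (0.0325).

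Of the 38 Hox genes, 17 were higher over all genes and 30 adjusted over the list alone, with 0 lower in either (camera adjusted p = 4.89e-10, adjusted p = 0.336 with an estimated correlation). In brackets from here on, counts over all genes come first and counts adjusted over the list alone second. The 3-prime group had a median of 2.49 (7 and 11 of 14 higher, camera adjusted p = 8.44e-05). The middle group had 1.67 (2 and 9 of 12 higher, 0.000276) and the 5-prime group 2.87 (8 and 10 of 12 higher, 6.96e-05). By cluster the medians were 1.96 in Hoxa (adjusted p = 0.00153), 1.80 in Hoxb (0.000936), 2.95 in Hoxc (0.000525) and 2.69 in Hoxd (0.000125). Without the shallow fl/fl library the median stayed at 1.79 (camera adjusted p = 1.24e-08), but 0 Hox genes passed over all genes and 8 adjusted over the list alone.

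**Figure D2:**
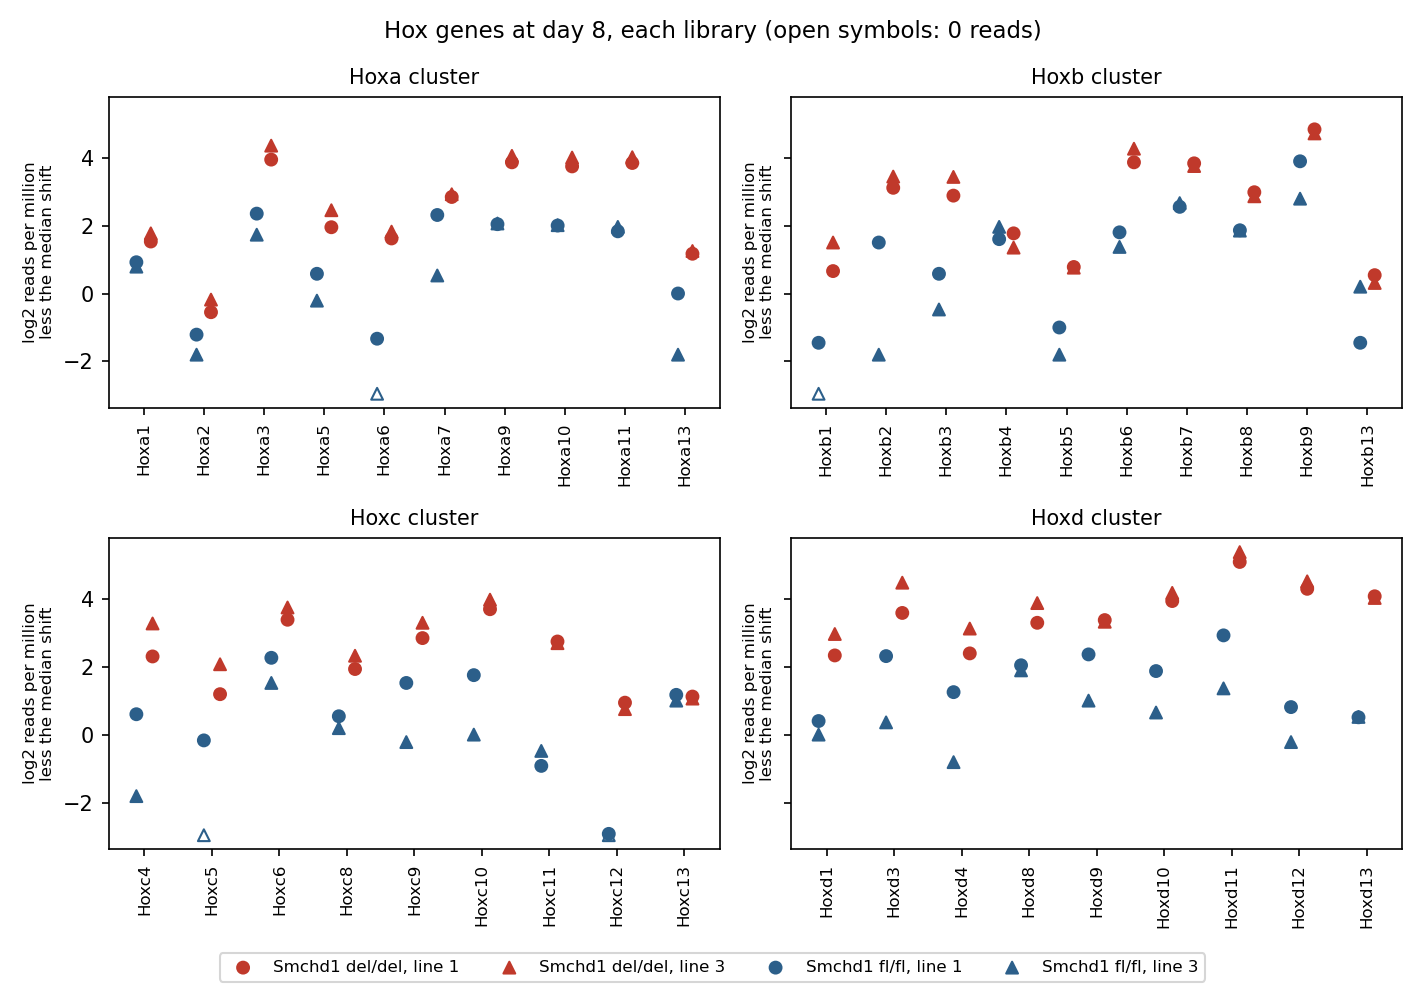
Each Hox gene at day 8 in the 4 libraries, as log2 RPM less the median shift of the library, by cluster and in order along it. Del/del libraries lie above fl/fl libraries for most genes, and 37 of 38 tested genes have a positive mean difference.

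The largest single increases in del/del at day 8 were in Cox4i2 (at least 28.6-fold, 0 reads in fl/fl, adjusted p = 0.00868), Islr (at least 15.4-fold, 0.0144), Ndufa4l2 (at least 7.94-fold, 0.0245) and Mybpc1 (5.41 ± 0.91, 0.00897). Cygb rose by 5.22 ± 0.76 (0.0072), Crym by 4.93 ± 0.72 (0.00729) and Crispld2 by 4.72 ± 0.88 (0.0137). Cygb, Crym and Crispld2 had 0 reads in the shallow fl/fl library. Their reads were 45.9-fold (17.8 to 169), 14.6-fold (9.87 to 22.4) and 21.7-fold (11.7 to 45.5) higher. Stra8, a retinoic acid responsive meiotic gene, had 1 read in fl/fl and rose 83.7-fold in reads (14.8 to 3320, adjusted p = 0.00396). The largest decreases were in Car6 (95.6-fold in reads, 16.3 to 3860, adjusted p = 0.0137), the placental hormone gene Prl3b1 (-5.72 ± 1.72, 0.0475), Lect2 (-5.70 ± 0.98, 0.00961) and Aoah (36.7-fold in reads, 9.38 to 315, 0.00194). Prl3b1 was uneven between lines, with 0 and 27 reads in del/del against 559 and 15 in fl/fl (line 1, then line 3). Ihh fell by 4.79 ± 1.27 (0.0326), the endothelial receptor gene Tie1 35.6-fold in reads (5.53 to 1490, 0.0149), Serpinb9c by 4.45 ± 0.76 (0.0096) and Slc6a12 by 4.41 ± 1.14 (0.0304). In reads Slc6a12 was 8.61-fold lower (4.91 to 16), less than its fitted 21.3-fold. Each of these 16 had both del/del libraries on 1 side of both fl/fl libraries, which the naming rule required and which is no further evidence. Without the shallow library 8 of them kept the call, namely Cox4i2, Islr, Mybpc1, Cygb, Stra8, Crym, Aoah and Serpinb9c, and the adjusted p of the other 8 was 0.0541 to 0.155.

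Over all genes, 1118 were higher and 991 lower at day 8 by limma, and 927 and 951 by voom. On the deposited scale, where the median gene lies 0.90 above 0, 3227 were higher (97.9%) and 68 lower, against 53% higher relative to the median gene. Without the shallow library 185 were higher and 114 lower relative to the median gene. Without the del/del day 5 library of line 3, 1765 were higher and 1579 lower. With array weights on the deposited scale 0 genes passed at day 8. On that scale the count was 579 or 237 without either del/del day 8 library (line 1 or line 3), 9882 without the fl/fl library of line 1 and 379 without that of line 3.

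Naive pluripotency genes were lower as a list at day 8. Of 23 naive genes, the network of the ground state, 9 were lower and 1 higher (12 and 1 adjusted over the list alone, median -0.91, camera adjusted p = 0.000227). Sox2 fell by 1.43 ± 0.22 (adjusted p = 0.00759), the threonine dehydrogenase gene Tdh by 2.09 ± 0.32 (0.00759), Nr5a2 by 2.33 ± 0.47 (0.0161) and Pou5f1 by 0.86 ± 0.17 (0.015). Of the primed list, Otx2 fell by 2.91 ± 0.69 (0.0241) while Lef1 rose by 1.61 ± 0.27 (0.0093) and Dnmt3a by 0.50 ± 0.11 (0.0213), and the list did not pass (adjusted p = 0.977). The epithelial genes Epcam (-1.43 ± 0.13, 0.00194) and Cdh1 (-1.68 ± 0.18, 0.00286) also fell; these 2 were chosen after their values were seen. Without the shallow library 2 naive genes were lower and 1 higher over all genes, with a median of -0.73; Sox2, Tdh, Lef1, Epcam and Cdh1 kept their calls, and Nr5a2, Pou5f1, Otx2 and Dnmt3a did not.

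Markers of extraembryonic tissue were lower in del/del at day 8. The trophoblast list had a median of -1.41 (6 and 6 of 12 lower, adjusted p = 0.00031), with Rhox6 falling by 1.88 ± 0.37 (0.015), Rhox9 by 2.36 ± 0.47 (0.0157), Krt7 by 2.25 ± 0.47 (0.017) and Krt18 by 1.85 ± 0.40 (0.019). The extraembryonic endoderm list had -1.26 (4 and 4 of 13 lower, adjusted p = 0.00501, adjusted p = 0.452 with an estimated correlation), with Col4a2 falling by 1.26 ± 0.29 (0.0209), Sparc by 1.22 ± 0.33 (0.035) and Lamb1 by 0.63 ± 0.17 (0.0327). The tight junction gene Cldn6 (-1.31 ± 0.21, 0.00839) and Trh (-1.85 ± 0.37, 0.0158) fell in the definitive endoderm list (median -1.45, 2 and 2 of 6 lower, adjusted p = 0.042). Without the shallow library 0 genes of these 3 lists passed over all genes, with medians of -1.54, -1.07 and -1.34. Of 12 fits without 1 library each, camera called the trophoblast list in 12, extraembryonic endoderm in 10 and definitive endoderm in 8 (adjusted p up to 0.188). The extraembryonic endoderm call was lost without the del/del (0.0938) or the fl/fl day 8 library of line 1, and that of definitive endoderm without either of these or either del/del day 5 library. Reads of some dense genes followed depth only weakly: Eef1a1 had 1680 to 2090, Eef2 4091 to 6789 and Hsp90ab1 3644 to 6132 in all 12 libraries. Folds of dense genes such as Krt18, Col4a1, Sparc and Cldn6 are therefore uncertain. Col4a1 lost its call with a read density trend removed (adjusted p = 0.0628, against 0.0314).

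Mesenchymal genes were higher in del/del at day 8. The fibroblast list had a median of 1.68 (4 of 14 higher and 1 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.0062), with Thy1 rising by 4.66 ± 0.99 (0.0181), Fbln2 by 1.81 ± 0.38 (0.0168) and Loxl1 by 1.54 ± 0.33 (0.0182), and Fn1 falling by 1.06 ± 0.25 (0.0235). Its median was 0.96 without the shallow library, with 0 genes higher and 1 lower by limma over all genes, 4 and 1 adjusted over the list alone, and camera called it (adjusted p = 0.0253). Paraxial mesoderm genes had 0.70 (3 and 3 of 15 higher, adjusted p = 0.0586), with Tcf15 rising by 1.53 ± 0.37 (0.0257) and Lfng by 2.35 ± 0.58. Of the NMP list (0.15, 2 and 2 higher and 1 and 1 lower of 17, adjusted p = 0.977), Evx1 rose by 2.11 ± 0.40 (0.0144). Sox2, a member of this list and of the neural progenitor list too, fell by 1.43 (0.00759). In lateral and intermediate mesoderm (-0.25, with a mean of 0.29, 2 and 2 higher and 1 and 1 lower of 8, adjusted p = 0.869), Hand2 rose by 4.22 ± 0.98 (0.0225) and Bmp4 by 1.60 ± 0.31 (0.0142), and Hand1 fell by 2.10 ± 0.43 (0.0161). Neural lists were mixed: Zic1 rose by 2.72 ± 0.45 (0.00864) and Olig2 fell by 2.79 ± 0.58 (0.0168) among neural progenitor genes (0.49, 4 and 5 higher and 2 and 2 lower of 15, adjusted p = 0.479). Nefm fell by 2.01 ± 0.42 among postmitotic neuron genes (-0.83, 1 and 1 higher and 2 and 2 lower of 6, adjusted p = 0.308). Of the genes named in this paragraph, Fn1, Sox2 and Zic1 kept their calls without the shallow library. The paraxial mesoderm list then had a median of 1.28.

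Signalling lists also parted the genotypes at day 8. Retinoic acid genes had a median of 1.24 (6 and 7 of 12 higher, adjusted p = 0.00501), with Crabp2 rising by 4.51 ± 0.98 (0.019), Rarb by 2.71 ± 0.67 (0.0265) and Rarg by 1.75 ± 0.22 (0.00498). Gdf11 and TGF-beta targets had 0.72 (6 and 7 higher and 2 and 2 lower of 15, adjusted p = 0.0154, adjusted p = 0.336 with an estimated correlation), with Tgfbi rising by 3.26 ± 0.58 (0.0116), Bambi by 1.90 ± 0.29 (0.00729) and Id2 by 1.27 ± 0.24 (0.0146). FGF and ERK targets had 0.50 (4 and 9 higher and 0 and 1 lower of 16, adjusted p = 0.0111), with Spry4 rising by 0.97 ± 0.16 (0.00883). Of Wnt targets (0.49, 4 and 5 higher and 1 and 1 lower of 17, adjusted p = 0.0897), Nkd2 rose by 3.43 ± 0.66 (0.0146) and Lgr5 fell by 3.12 ± 0.79 (0.0292). Cell cycle genes had 0.67, all 24 positive (8 and 12 higher, adjusted p = 7.96e-06), with Ccnb2 rising by 0.88 ± 0.20 (0.0213) and Top2a by 1.00 ± 0.26 (0.0302). Targets of p53 had -0.52 relative to the median gene and 0.36 on the deposited scale (9 and 10 of 21 lower, adjusted p = 8.44e-05), with Trp53inp1 falling by 1.14 ± 0.19 (0.00839) and Mdm2 by 1.06 ± 0.22 (0.0172). When the shallow library was left out, Rarb, Rarg, Bambi, Spry4 and Trp53inp1 kept their calls and the other genes named in this paragraph did not. The medians were then 1.26 for retinoic acid genes, 0.64 for Gdf11 and TGF-beta targets, 0.35 for FGF and ERK targets, 0.32 for cell cycle genes and -0.29 for p53 targets, and camera called all 5. The Gdf11 and TGF-beta call was lost without the fl/fl day 8 library of line 1 (0.108).

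Imprinted genes, a known class of SMCHD1 targets, went both ways at day 8 (7 higher and 5 lower of 60, 10 and 7 adjusted over the list alone, median -0.07, adjusted p = 0.768). Mest rose by 2.74 ± 0.42 (0.00743), and in the Snrpn cluster (0.17, 3 and 3 of 8 higher, adjusted p = 0.141) Peg12 rose by 2.75 ± 0.46 (0.00883), Mkrn3 by 1.58 ± 0.33 (0.017) and Ndn by 0.93 ± 0.23 (0.0281). Dio3 fell by 3.81 ± 0.57 (0.00729) and Sfmbt2 by 2.16 ± 0.28 (0.00545). In the Igf2r cluster 0 of 4 genes passed by limma (0.05, with a mean of -0.10, adjusted p = 0.878). The protocadherin clusters, silenced by SMCHD1 in other tissues, had 1 tested gene each, none past the test: Pcdhac1 at 0.82, Pcdhb22 at 0.74 and Pcdhga11 at 0.17. With no filter, on the deposited scale, camera called the Pcdh beta list higher in del/del at day 8 (adjusted p = 5.15e-05) and over the days (4.86e-05), but not at day 1 (0.521) or day 5 (0.0918), and its effect moved between day 1 and day 8 (3.14e-06). These calls rest on the preset correlation: with an estimated one, added after they were seen, the adjusted p was 0.549 at day 8, 0.42 over the days and 0.426 for day 8 against day 1. Relative to the median gene, with no filter, it was 0.00047, 0.00292 and 0.000301 at the preset and 0.37, 0.455 and 0.389 at the estimated correlation. Pooled after this was seen, the 22 Pcdh beta genes had 330 and 396 reads in del/del and 89 and 23 in fl/fl at day 8, 2.92-fold more relative to the median gene (2.39 to 3.59), with all 22 higher, against 1.23-fold (0.708 to 2.19) at day 1 and 1.39-fold (0.932 to 2.07) at day 5. The 21 under the filter had 181 and 236 against 36 and 3 reads at day 8 (4.81-fold, 3.46 to 6.86). Of germline genes (0.65, 3 and 6 higher and 1 and 2 lower of 20, adjusted p = 0.0586), Zcwpw1 rose by 2.65 ± 0.37 (0.00677) and Sycp3 by 1.41 ± 0.27 (0.0146). Mest, Peg12, Dio3, Sfmbt2 and Zcwpw1 kept their calls without the shallow library, and Mkrn3, Ndn and Sycp3 did not.

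Among chromatin genes at day 8, the Polycomb list had a median of 0.01 (2 and 2 higher and 4 and 4 lower of 31, adjusted p = 0.746), with Ezh2 rising by 0.83 ± 0.17 (0.0168) and Cbx7 falling by 1.28 ± 0.21 (0.0081). In the DNA methylation and silencing list (0.18, 2 and 4 higher and 1 and 1 lower of 23, adjusted p = 0.308) Suv39h1 rose by 0.93 ± 0.19 (0.0165) and Dnmt3l fell by 1.35 ± 0.23 (0.00963). Chromatin architecture genes had 0.39 (4 of 22 higher, 4 higher and 2 lower adjusted over the list alone, adjusted p = 0.0262), with the condensin genes Ncapd2 rising by 1.05 ± 0.21 (0.015) and Ncapg by 1.68 ± 0.44 (0.032); without the shallow library the list did not pass, with a median of 0.05. Of the remaining lists, none passed: interferon response (-0.57, 2 and 2 of 15 lower, Irf7 falling by 1.86 ± 0.48), stress and heat shock (-0.48, 3 and 3 higher and 2 and 7 lower of 18, Chac1 rising by 3.10 ± 0.48), glycolysis and hypoxia (-0.15, with a mean of 0.21, 4 and 5 higher and 3 and 3 lower of 24, Ero1l falling by 0.86 ± 0.20), endothelium and blood (-0.82, bound -0.51, 0 and 1 higher and 1 and 3 lower of 9), 2-cell-like (-0.48, bound -0.16, 1 and 1 of 8 lower) and Y-linked (0 of 5 by limma). Hist1h2bc fell by 1.34 ± 0.37 (0.0373), 1 of 2 replication histones tested, and no mitochondrial transcript was testable. Of the genes named in this paragraph from lists that camera tested, Cbx7, Dnmt3l and Chac1 kept their calls without the shallow library. Over all lists, 147 list genes were called at day 8 and 24 of them without it. No chromosome passed camera in any comparison of genotypes.

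**Figure D3:**
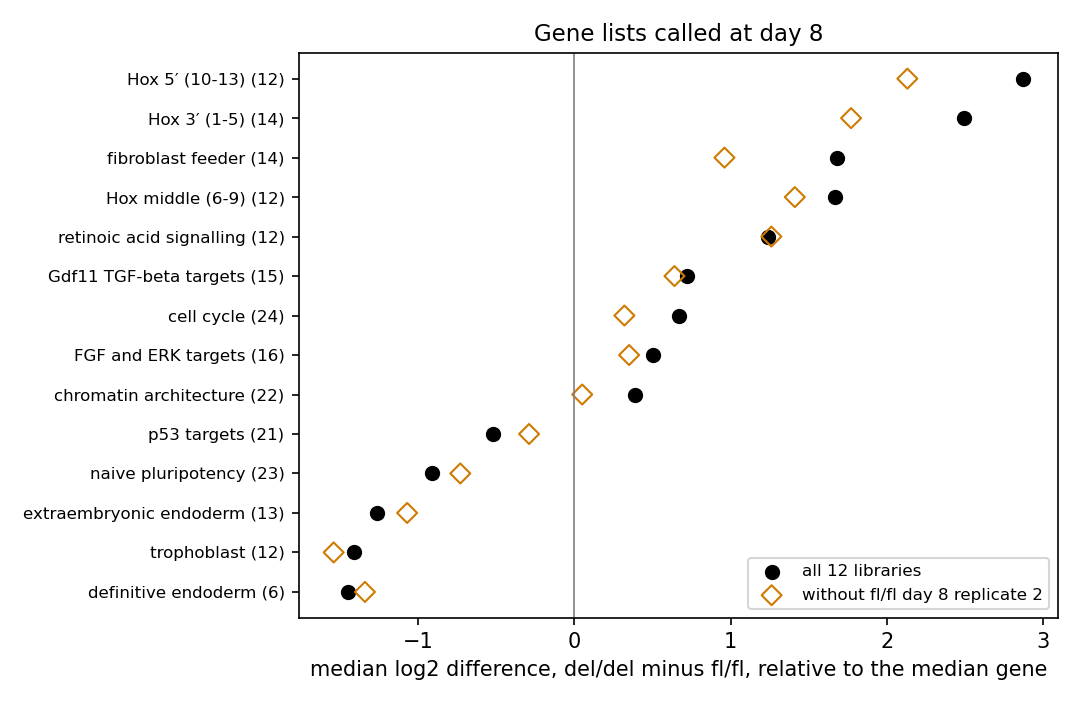
Median log2 difference of del/del minus fl/fl at day 8 for lists that camera called, with all 12 libraries and without the shallow fl/fl library. The called lists of all Hox genes and of the Hox clusters are not drawn. The 3-prime, middle and 5-prime Hox lists lie at 2.49, 1.67 and 2.87 with all libraries and at 1.77, 1.41 and 2.13 without it.

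Averaged over the 3 days, 5 genes were higher and 10 lower relative to the median gene, and 5 and 1 on the deposited scale. Lix1 rose by 2.01 ± 0.29 (adjusted p = 0.0401), and the lipid transporter gene Slc27a2 fell by 1.76 ± 0.25 (0.0401) and Aoah by 1.87 ± 0.27 (0.0401). The mean of Aoah rests mostly on day 8, where it was at -5.43, a change of -5.56 from day 1. Higher on the deposited scale alone were Cox4i2 (3.66 ± 0.63, 0.0514), Hoxb3os (2.45 ± 0.47, 0.0627), Cxcl12 (1.82 ± 0.41, 0.0639) and Ptn (1.91 ± 0.43, 0.0648), with deposited adjusted p of 0.00637, 0.046, 0.046 and 0.046. Clca6 was lower by 2.15 ± 0.57 (0.0835). Chosen after their values were seen, the other 4 genes higher were Adamts10 (1.34), Bambi (1.06), the macroH2A gene H2afy2 (0.83) and X99384 (0.67). The 7 others lower, besides Smchd1, were Camk2b (-1.29), Zfp459 (-1.22), Bspry (-0.98), L1td1 (-0.81), Cdh1 (-0.72), St14 (-0.69) and Epcam (-0.60). With a replicate block only Smchd1 remained of these 15. Without the shallow library 2 genes were higher and 2 lower, and without the del/del day 5 library of line 3, 0 and 12. The 6 calls on the deposited scale became 94 and 1 without the del/del day 5 library of line 1 or line 3, 1 and 0 without that of fl/fl, and 4366 and 36 without the fl/fl day 8 library of line 1 or line 3.

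Camera called 22 lists over the days. Hox genes had a median of 0.86 (36 of 38 positive, 10 higher adjusted over the list alone, adjusted p = 5.35e-08, adjusted p = 0.426 with an estimated correlation). Naive genes had -0.53 (11 lower and 1 higher adjusted over the list alone, 0.000283), trophoblast genes -0.58 (5 lower, 0.00054), extraembryonic endoderm genes -0.56 (3 lower, 0.00532), p53 targets -0.19 (5 lower, 0.0019, 0.03 on the deposited scale), cell cycle genes 0.29 (9.44e-05) and the Snrpn cluster 0.14 (3 higher, 0.0324). Retinoic acid genes had 0.51 (0.0179) and Gdf11 and TGF-beta targets 0.44 (6 higher and 2 lower, 0.0206). Also called were definitive endoderm (-0.62, 0.0324), fibroblast (0.54, 0.0213), paraxial mesoderm (0.44, 0.0187), Wnt target (0.28, 0.046), stress and heat shock (-0.26, 0.0454) and chromatin architecture genes (0.19, 0.0438), the other 7 being parts of the Hox list. Of 12 fits without 1 library each, the Hox, naive, trophoblast, p53, retinoic acid and cell cycle lists kept their calls in 12. Extraembryonic endoderm and Gdf11 and TGF-beta targets did so in 11, the Snrpn cluster in 10, paraxial mesoderm and fibroblast genes in 9, definitive endoderm in 8, stress and heat shock in 6, and Wnt targets and chromatin architecture in 4.

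The time course within fl/fl cells shows what the protocol does without the deletion. From day 1 to day 5 the caudal programme rose: T, the brachyury gene of nascent mesoderm, by 8.15 ± 0.43 (adjusted p = 1.78e-06), Cdx1 by 6.62 ± 0.32 (8.64e-07), Cdx2 by 5.09 ± 0.28 (1.88e-06) and the Wnt feedback gene Axin2 by 4.08 ± 0.15 (2.88e-07). Hoxb6 rose at least 96.3-fold and Dkk4 at least 59.4-fold from 0 reads. Nkx6-1 (377-fold in reads, 67.3 to 14900) and Ctsh (417-fold, 115 to 3450) rose too. Pluripotency and epiblast genes fell, Fgf5 by 6.46 ± 1.21 (0.00172), Fgf4 by 6.15 ± 0.40 (4.28e-06), Tdgf1 by 3.67 ± 0.45, Pou3f1 by 3.47 ± 0.36 (4.7e-05) and Sox2 by 1.57 ± 0.22. The largest decreases also took in Spna1 (-7.07 ± 0.97), Kirrel2 (-6.78 ± 0.97), Enpp3 (-6.67 ± 0.49) and Foxi3 (-6.37 ± 0.80).

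In fl/fl, 3234 genes were higher and 2513 lower at day 5 than at day 1 by limma (1221 and 1436 on the deposited scale). Of 38 Hox genes 33 were higher over all genes and 34 adjusted over the list alone, with a median of 5.25 (bound 5.13, camera adjusted p = 1.2e-13, adjusted p = 0.242 with an estimated correlation). Wnt targets had 3.59 (15 and 15 of 17 higher, adjusted p = 8.44e-10), the NMP list 3.31 (12 and 12 higher, 3 and 3 lower, 0.00017), extraembryonic endoderm genes 2.27 (8 and 9 higher, 0.00017), trophoblast genes 1.76 (8 and 9 higher, 0.0159) and fibroblast genes 1.64 (8 and 8 higher, 0.00562). Naive genes had -1.05 (3 and 3 higher, 13 and 14 lower, 0.00029), primed genes -2.04 (2 and 2 higher, 11 and 11 lower, 0.000462), 2-cell-like genes -4.08 (6 and 7 lower, 0.00449) and germline genes -1.50 (2 and 2 higher, 9 and 11 lower, 0.00766). Tet1 fell by 3.19 ± 0.18 among DNA methylation genes (-0.89, 1 and 1 higher, 15 and 18 lower, 3.71e-07), and Ccne1 by 1.10 ± 0.14 among cell cycle genes (-0.95, 20 and 20 lower, 1.2e-07). The noncoding gene Airn rose by 2.63 ± 0.22 in the Igf2r cluster (1.94, 3 and 3 of 4 higher, 0.0159), and Snrpn fell by 1.76 ± 0.17 in its own (-1.24, 1 and 1 higher, 5 and 5 lower, 0.02).

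From day 5 to day 8 in fl/fl, the caudal genes went down again and mesenchymal genes up. Fgf8 fell by 4.98 ± 0.85 (adjusted p = 0.0098), T by 2.29 ± 0.43 (0.0143), Evx1 by 2.48 ± 0.40 (0.00863) and Tbx6 by 4.30 ± 0.97 (0.0286), and Msgn1, left with 1 read, 87.1-fold in reads (15.4 to 3460, 0.018). Col3a1 rose by 4.16 ± 0.70 (0.00925), Twist1 by 2.31 ± 0.26 (0.00305), the matrix gene Tnc by 6.17 ± 1.25 (0.0194) and the BMP antagonist gene Grem1 by 5.18 ± 0.66 (0.00345). Lce1h (5.93 ± 0.78), Lect2 (5.89 ± 0.98) and Doxl2 (5.57 ± 1.09) rose and Smpd3 (-4.62 ± 0.60) and Tnfrsf8 (-4.49 ± 0.54) fell. The counts were 443 higher and 503 lower by limma (24 and 152 on the deposited scale, 206 and 229 without the shallow library). The deposited count of 176 became 2 and 0 without the fl/fl day 5 library of line 1 or line 3, and 7188 without the fl/fl day 8 library of line 1. NMP genes had -2.07 (9 and 14 of 17 lower, adjusted p = 1.22e-08, adjusted p = 0.0789 with an estimated correlation), paraxial mesoderm genes -1.28 (5 and 6 lower, 0.00301), fibroblast genes 2.35 (9 and 11 of 14 higher, 4.46e-08) and cell cycle genes -0.80 (10 and 21 lower, 2.98e-11). The interferon list had 1.75 (5 and 10 higher, 0 and 1 lower, 1.39e-05), with Usp18 rising by 3.74 ± 0.52 (0.00467), and the Gdf11 and TGF-beta list 1.09 (5 and 9 higher, 0 and 1 lower, 3.97e-05), with Pmepa1 rising by 1.65 ± 0.26. The 5-prime Hox genes had 1.57 (bound 1.43, 1 and 2 higher, 0.00124) and the 3-prime ones -1.01 (1 and 1 lower, 0.0469), with Hoxb1 falling by 3.13 ± 0.73. The 3-prime call was lost without the shallow library (0.469) or the fl/fl day 5 library of line 1. The calls of 5-prime Hox (0.0603) and paraxial mesoderm genes (0.0912) were lost without the fl/fl day 8 library of line 1, and the latter also without that of day 5.

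From day 1 to day 5 in del/del, Hoxb6 rose by 9.02 ± 0.57 (adjusted p = 2.43e-06), Hoxb8 by 8.58 ± 0.49, T by 7.45 ± 0.43 (1.67e-06), Cdx1 by 6.14 ± 0.32 and Axin2 by 3.62 ± 0.15 (3.46e-07). Hoxd9 rose by 8.61 ± 0.66, Hoxa3, with 27.1% shared exons, by 8.60 ± 0.73 and Hoxa9 at least 86.8-fold. Slc27a2 fell by 8.04 ± 0.43 (1.13e-06), Otx2 changed by -7.31 ± 0.69 (2.5e-05), and Fgf4 fell by 5.86 ± 0.40 and Sox2 by 1.61 ± 0.22. Spna1 (-8.34 ± 0.97), Cyp2b23 (-6.99 ± 0.94) and Insc (212-fold in reads, 37.8 to 8380) fell too. In all 2987 genes were higher and 2574 lower by limma (826 and 4928 on the deposited scale, where the median gene fell). Hox genes had a median of 6.04 (bound 5.62, 34 and 35 of 38 higher, adjusted p = 2.93e-16), Wnt targets 4.34 (16 and 16 of 17 higher, 8.52e-11), naive genes -1.61 (3 and 3 higher, 17 and 17 lower, 4.58e-05) and germline genes -2.01 (1 and 2 higher, 15 and 15 lower, 7.04e-05).

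From day 5 to day 8 in del/del, posterior Hox genes rose: Hoxd12 by 7.22 ± 0.79 (adjusted p = 0.000516), Hoxc11 by 6.27 ± 0.74 (0.000744), Hoxd13 by 5.69 ± 0.73 (0.0011) and Hoxa11 by 4.02 ± 0.48 (8e-04). The Nodal antagonist gene Lefty1 rose by 3.54 ± 0.36 (0.000386), Tgfbi by 4.68 ± 0.58 (0.000974) and Twist1 by 3.33 ± 0.26 (0.000133). Pgm5 rose by 7.26 ± 1.03 (0.0019), Lin7a 232-fold in reads (41.5 to 9200), Slitrk6 at least 39.9-fold and Dnm3os at least 37.8-fold. T fell by 3.54 ± 0.43 (0.00084), Fgf8 by 5.29 ± 0.85 (0.00383), Foxb1 by 5.08 ± 1.31 (0.0312) and Tnfrsf8 by 5.23 ± 0.54. Aoah (38.7-fold in reads, 10.1 to 330) and Car6 (118-fold, 20.4 to 4730) fell as well. The counts were 1018 higher and 657 lower by limma (1096 and 51 on the deposited scale, 1521 and 1343 without the shallow fl/fl library, which enters through the shared spread). The 5-prime Hox list had 3.56 (9 and 11 of 12 higher, adjusted p = 4.21e-09), the 3-prime list 0.42 (0.574), Gdf11 and TGF-beta targets 1.36 (12 and 13 of 15 higher, 1 and 1 lower, 2.63e-08), fibroblast genes 3.18 (11 and 11 higher, 1.01e-08) and NMP genes -1.42 (9 and 12 lower, 1.01e-08). Cell cycle genes had -0.43 relative to the median gene and 0.27 on the deposited scale (4 and 6 lower, 0.000883, and 0.143 without the del/del day 5 library of line 3).

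Whether the genotype effect itself changed between days was tested with the interactions. Between day 1 and day 8, the difference of Wnt4 between genotypes moved by 5.45 ± 0.63 (adjusted p = 0.027), and Mmp11 and Aoah, chosen after their values were seen, changed by 2.12 ± 0.26 (0.0316) and -5.56 ± 0.65 (0.027). Mmp11, a matrix metalloproteinase gene, also changed by 2.39 ± 0.26 between day 5 and day 8 (0.0306). Limma thus called 2 genes higher and 1 lower for day 8 against day 1, 1 higher for day 8 against day 5 and 0 for day 5 against day 1 (358 at an unadjusted p under 0.05, 231 and 0 called on the deposited scale, 0 by voom). With a replicate block, which pairs the lines, all 4 calls were lost (adjusted p = 0.0521 for the 3 genes of day 8 against day 1 and 0.0554 for Mmp11 at day 8 against day 5). Mmp11 and Aoah lost theirs for day 8 against day 1 without the shallow library too (0.0509). The Hox list moved by 2.50 between day 1 and day 8 (adjusted p = 1.77e-11), by 0.76 between day 1 and day 5 (5.69e-05) and by 1.58 between day 5 and day 8 (3.08e-05), so its rise with time in del/del passed at the preset correlation, against an adjusted p of 0.308, 0.869 and 0.573 with an estimated correlation. Its call between day 1 and day 5 was lost without the del/del day 5 library of line 3 (0.672), and that between day 5 and day 8 without the del/del day 5 library of line 1 (0.182). Without the del/del day 5 library of line 3, 116 genes were higher and 98 lower for day 8 against day 1, and 21 and 17 for day 8 against day 5.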

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

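All tests of explanations in this part were chosen after the results were seen; the interactions themselves were planned. What singles out the genes and lists of the next 2 paragraphs is that the genotype effect differed between days by a test of the difference.

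The deposited scale called 3 genes for day 8 against day 1 and 26 for day 8 against day 5. Relative to the median gene the 5 with the smallest p of each (all 3 of the former) changed as follows, with the deposited adjusted p last. For day 8 against day 1, Wnt4 changed by 5.45 ± 0.63 (0.0305), Tril by 5.31 ± 1.00 (0.0369) and Stra8 by 4.67 ± 0.83 (0.0305), of which Wnt4 passed on the relative scale. For day 8 against day 5, Stra8 changed by 5.91 ± 0.83 (0.000838), Bcl11a by 3.94 ± 0.72 (0.0474), Igfbp3 by 3.32 ± 0.44 (0.0208), Bai2 by 3.16 ± 0.43 (0.0474) and Mmp11 by 2.39 ± 0.26 (0.0474), of which Mmp11 passed on the relative scale. With a replicate block on that scale, which pairs the lines, neither passed (adjusted p = 0.0521 for Wnt4 and 0.0554 for Mmp11).

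Relative to the median gene, camera called 19 lists for day 8 against day 1 and 14 for day 8 against day 5 at the preset correlation. Among those for day 8 against day 1, given by the change of their median, were the 5-prime Hox genes (2.77), all Hox genes (2.5), naive pluripotency (-0.9), extraembryonic endoderm (-1.01), trophoblast (-1.45), fibroblast feeder (1.88), p53 targets (-0.41), FGF and ERK targets (0.65), retinoic acid signalling (1.13) and cell cycle (0.71). Among those for day 8 against day 5 were the 5-prime Hox genes (2.54), all Hox genes (1.58), naive pluripotency (-0.71), trophoblast (-1), germline (1.06), p53 targets (-0.41), FGF and ERK targets (0.39), retinoic acid signalling (1.2) and cell cycle (0.46). On the deposited scale, where the median gene moved by 0.73 and 1.29, the medians of p53 targets were 0.31 and 0.85, and those of naive pluripotency and trophoblast for day 8 against day 5 were 0.54 and 0.25. None passed with an estimated correlation. Without the del/del day 5 library of line 1, camera called 3 lists for day 8 against day 5, namely 5-prime Hox genes, p53 targets and germline. The first 2 kept their calls without any 1 library (adjusted p up to 0.0088 and 0.0113), and germline lost its call without the del/del day 5 library of line 3 (0.073). For day 8 against day 1 there were 18 to 21 lists, and that of extraembryonic endoderm was lost without the del/del (0.222) or the fl/fl day 8 library of line 1.

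Hox genes were higher in del/del at day 8 against either fl/fl library (median 1.78 against line 1 and 2.61 against line 3). The median of 1.79 without the shallow library argues against that library as the whole source, though with 1 control left 0 Hox genes passed over all genes, and the 2.1 with a GC and length trend removed argues against those trends. A later stage of the same time course in del/del stays open: genes that fell by over 1 log2 from day 5 to day 8 in both genotypes of 1 line were lower in del/del at day 8 in the other, by -0.83 (335 genes chosen in line 1, measured in line 3, 30.7% of them above 0) and -0.33 (317 genes, the reverse, 38.2% above 0), and genes that rose in both were higher (0.95 and 0.58). Each of these medians compares 1 del/del with 1 fl/fl library, so it carries no spread between samples. Against this as the whole of the difference, cell cycle genes were lower at day 8 than at day 5 (-0.80 in fl/fl, -0.43 in del/del, the latter 0.27 on the deposited scale and not called without the del/del day 5 library of line 3), yet higher in del/del at day 8 (0.67). This was 0.32 without the shallow library, camera still called the list (0.000461), and 0 of its 8 genes called by limma kept the call, so this is weak evidence. The 3-prime Hox genes, 2.49 higher in del/del at day 8, decide nothing here: they had -1.01 between these days in fl/fl, a call lost without the shallow library (0.469) or the fl/fl day 5 library of line 1, and 0.42 in del/del (0.574). The hypothesis that SMCHD1 restrains Hox genes directly, and effects of transduction and selection, may add to it and were not tested.

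Trophoblast and extraembryonic endoderm genes were lower in del/del at day 8 against either fl/fl library (median of both lists -1.47 against line 1 and -1.01 against line 3, and -1.26 against both, over 25 genes). Without the shallow library the median was -1.46, and with the read density trend removed it was -1.11. That removal cannot exclude a ceiling on abundant genes: after it Eef1a1, whose reads hardly changed between libraries, still lay at -1.16, and Eef2 at -0.62. More cells of every other type in fl/fl would lower the mesenchymal list too, but the fibroblast list was at 1.68. The mean of both del/del libraries was higher on this list than either fl/fl library (median 0.96 against line 1 and 2.08 against line 3). This speaks for mesenchymal genes only. The naive pluripotency list (-0.74 against line 1 and -1.16 against line 3) and the definitive endoderm list (-1.34 and -1.19) were lower too. A wider change in the mix of cells therefore stays open. Fewer cells of the extraembryonic kind in del/del is a candidate explanation that bulk RNA leaves open; an abundant marker, Krt18, had 724 to 3121 reads in all libraries, 13 of the 25 genes had a relative log2 RPM above 0 in every day 1 library, and 4 are in another list too, so these genes are not specific to such cells.

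Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty and Zfy1) had 2 to 42 reads in the 6 libraries of line 1 (0.335 to 6.55 per M gene reads) and 261 to 2724 in those of line 3 (163 to 335), in both genotypes and at every day, so the difference lies between lines. The lowest share in line 3 was 24.9 times the highest in line 1, so no library carries the other line's number. A second active X chromosome in line 1, as in a female line, would raise X-linked genes, but X-linked less autosomal expression differed by 0.024 between the lines at day 1 (191 X-linked genes). Loss of the Y chromosome, or of a copy of the X chromosome in a female line, in line 1 is a hypothesis that these data could not separate, and the karyotype was not analysed here.

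Of the splits of libraries within days, 100 of 108 were drawn. On the deposited scale 3 of the 100, the real one included, called as many genes over the days as the real one, which called 6. The highest other called 20, and a split that calls several times more points to structure besides genotype. Libraries were swapped within each day on its own, while each of the 2 lines was split into genotypes before the time course. The splits therefore cannot exclude chance on either scale. Relative to the median gene only the real split, 1 of 100, called 15, and the highest other called 6. Among the 30 that part all 6 pairs of a line, the real one included, 2 called as many on the deposited scale and 1 relative to the median gene. The highest others were 20 and 0, and chance is not excluded with pairs kept either. Y-linked genes and splits were looked at besides.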

How the results depend on the processing

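Voom, the crossed pairing, the relative scale with a block, a library left out, a trend removed or no filter, and the estimated correlation with no filter were added after the data were seen, the other settings before, and for each departure below the cause was not tested unless stated. On the deposited scale the fit called 0 genes at day 1, 0 at day 5, 3295 at day 8, 6 over the days, 0, 3 and 26 for the interactions (day 5 and day 1, day 8 and day 1, day 8 and day 5), 2657 and 176 in fl/fl and 5754 and 1147 in del/del for day 5 against day 1 and day 8 against day 5, with Smchd1 at -2.69, -2.45 and -1.55. Counts that moved by over 1.5 times follow, with Smchd1 where its call moved.

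With a replicate block, pairing the lines, the counts were 33 over the days, 34 (day 8 and day 1) and 84 (day 8 and day 5), and on the relative scale with the block 1 at day 1, 1678 at day 8, 1 over the days, 0 and 0 for these interactions, and 5558 and 781 for the fl/fl steps, with Smchd1 at -2.84 at day 1. At day 5 the relative scale called Smchd1 alone (-2.07), and with the block on that scale this call was lost (adjusted p = 0.137, range 0.0095 to 0.205 over the settings on that scale). With crossed pairing the counts were 1 at day 1, 450 over the days, 5 and 0 for the interactions, and 5806 and 1057 for fl/fl, with Smchd1 at -2.84. Crossed pairing swaps the line numbers of the del/del libraries at day 5 and day 8. The Y-linked reads given above contradict that swap, so these counts are no valid alternative to those with the block.

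With no filter the counts were 2 over the days, 0 and 2 for the day 8 interactions and 85 for fl/fl day 8 against day 5. The stricter filter gave 22 over the days and 13 (day 8 and day 1). A pseudocount of 1 gave 353 over the days, 1, 396 and 755 for the interactions and 2018 for del/del day 8 against day 5. Without the trend there were 1867 genes at day 8, 19 and 47 for the day 8 interactions and 111 for fl/fl day 8 against day 5, and Smchd1 at day 8 (-1.55) lost its call. The robust fit gave 28 over the days, 27 and 96. Array weights gave 56 at day 1, 0 at day 8, 1 over the days, 0 and 0 for the interactions, 0 for fl/fl day 8 against day 5, and 9232 and 5759 in del/del; Smchd1 gained a call at day 1 (-2.69) and lost it at day 8 (-1.55). Fits of 1 day only, with fewer libraries, gave 1 gene at day 1 and 1004 at day 8, with Smchd1 at -2.69 and -1.55.

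The median of log ratios gave 1 gene at day 1, 1 at day 5, 2109 at day 8, 15 over the days, 1 (day 8 and day 5), and 5747 and 946 in fl/fl, with Smchd1 at -2.84 and -2.07; it moves the median gene to 0, which ends the excess of higher genes at day 8. Quantile normalization gave 1, 1, 154 over the days, 11 and 3, 5727 and 1219 in fl/fl and 1983 for del/del day 8 against day 5, with Smchd1 at -2.69 and -2.08. Voom gave 1 at day 1, 1878 at day 8, 32 over the days, 1 and 0 for the interactions, 6681 and 754 in fl/fl and 2473 in del/del, with Smchd1 at -2.84. On the relative scale without the shallow library the counts were 1, 1, 299, 3 (day 8 and day 5), 6787 and 435 in fl/fl and 2864 for del/del day 8 against day 5, with Smchd1 at -2.84 and -2.08. Without the del/del day 5 library of line 3 they were 1 at day 1, 12 over the days, 214 (day 8 and day 1), 6597 and 1525 in fl/fl and 1918 in del/del, with Smchd1 at -2.85. With the GC and length trend removed they were 1, 1, 122 over the days, 5 and 3, 6175 and 1192, and 2143, with Smchd1 at -2.85 and -1.99. With the read density trend removed they were 1, 1, 3 (day 8 and day 5), 6222 and 1051, with Smchd1 at -2.89 and -2.02.

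Lists called on the deposited scale numbered 14 at day 1, 12 at day 5, 22 at day 8, 20 over the days, 12, 22 and 19 for the interactions, 26 and 18 in fl/fl and 27 and 13 in del/del. At day 1 there were 3 without the filter, 7 without it on the relative scale (and 7 for day 5 and day 1), 7 with the median of log ratios or with its block, 6 without the shallow library or the GC and length trend and 8 without the density trend, and for day 8 and day 5 11 without the shallow library. An estimated correlation left 0 in all 11 comparisons, and 1 on the relative scale, for del/del day 8 against day 5. With no filter it left 0 on the deposited scale in all 11, and on the relative scale 1 and 0 in fl/fl, 1 and 5 in del/del and 0 in the other 7. Fry called 0 at day 1 and day 5, over the days and for the 3 interactions, 15 and 1 in fl/fl and 5 for del/del day 8 against day 5.

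Leaving out each library in turn, a lone library being assumed to vary like the other groups, gave 0 to 1 genes at day 1, 0 to 1 at day 5, 237 to 9882 at day 8, 0 to 4366 over the days, 0 to 0, 0 to 6444 and 1 to 10299 for the interactions, 1097 to 5624 and 0 to 7188 in fl/fl and 2003 to 8608 and 315 to 4750 in del/del. The highest counts came mostly without the fl/fl day 8 library of line 1. Smchd1 ranged over -2.86 to -2.51, -3.06 to -1.83 and -2.35 to -0.74. Lists on the deposited scale ranged over 6 to 14, 4 to 19, 15 to 23, 10 to 23, 5 to 17, 21 to 23, 11 to 22, 25 to 27, 14 to 18, 26 to 29 and 11 to 18, in the order above, and on the relative scale over 3 to 8, 0 to 13, 17 to 20, 16 to 22, 3 to 12, 18 to 21, 3 to 22, 22 to 23, 10 to 15, 20 to 22 and 8 to 15. Over the alternatives that leave out no library in turn, values of named genes kept their direction and call in 957 cases, stayed uncalled in 199, lost the call in 162 and gained it in 17, and when libraries were left out in turn in 733, 149, 107 and 7; no named gene reversed, nor did Smchd1. List medians did turn sign between the scales, among them p53 targets at day 8 (-0.52 relative, 0.36 deposited), cell cycle genes for del/del day 8 against day 5 (-0.43 and 0.27), and naive pluripotency (-0.71 and 0.54) and trophoblast (-1 and 0.25) for day 8 and day 5. No chromosome was called under the replicate block.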

Other observations

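Genes in this part were chosen after their values were seen, and no epithelial list was fixed or tested. At day 8 in del/del, Epcam fell by 1.43 ± 0.13 (adjusted p = 0.00194) and Cdh1 by 1.68 ± 0.18 (0.00286), with the keratin gene Krt18 (-1.85 ± 0.40), Cldn6 (-1.31 ± 0.21) and Krt7 (-2.25 ± 0.47). Of the fibroblast list, Thy1 (4.66 ± 0.99), Fbln2 (1.81 ± 0.38) and Loxl1 (1.54 ± 0.33) rose and Fn1 fell by 1.06 ± 0.25 (0.0235). Without the shallow library Epcam was at -1.38, Cdh1 at -1.74, Krt18 at -1.03, Cldn6 at -1.15 and Krt7 at -1.65. Thy1 was then at 2.93, Fbln2 at 1.17, Loxl1 at 1.3 and Fn1 at -0.54. Of all these genes, Epcam, Cdh1 and Fn1 kept their calls and the others lost them. The folds of Krt18 and Cldn6, as dense genes, are uncertain besides. From day 5 to day 8 Twist1 rose by 2.31 ± 0.26 in fl/fl and by 3.33 ± 0.26 in del/del.

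Gdf11, the gene of the added factor, was higher in del/del at day 8 by 1.10 ± 0.30 (adjusted p = 0.0351) and Lin28b by 2.72 ± 0.69 (0.0287), and neither passed without the shallow library (0.173 and 0.11).

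The fl/fl day 8 library of line 3, whose column name alone holds the word merge, had 301 genes at 1 read, 906 at 2, 382 at 3 and 699 at 4, a ratio of genes at 2 reads to genes at 1 of 3.01, against 0.79 to 0.98 in the other 11 libraries. Reads entered double would give such an excess of even numbers, in which case its depth is overstated and intervals that use it are too narrow; this was not tested. Its 50 highest genes held 7.4% of gene reads, against 4.1 to 4.9% elsewhere. Chi-square per degree of freedom between replicates was 3.6 and 2.8 at day 1 (del/del, fl/fl), 19 and 7.9 at day 5 and 8.1 and 13.6 at day 8. Hsp90ab1 had 1.22 to 2.04 reads per exonic base and Eef2 1.23 to 2.04 in all libraries, while H19 had 2346 to 5827 reads. Genes over 1 read per base had a median of -0.58 at day 8 (62 genes) and those at 0.5 to 1 of -0.33 (400 genes). Xist had 44 to 171 reads in line 1 and 20 to 127 in line 3.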
